A study of Mus musculus with 550 samples.

How the data were processed

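Messenger RNA of 7 organs was measured on 550 Affymetrix mouse arrays, 1 array per animal and organ, in 77 groups of organ, time and treatment. The deposited values are log2 probe set summaries, and per the labels RMA, GCRMA, R 2.11.1 and limma 3.4.5 were used, with no role or order given. Arrays of an organ and time share a floor and near-identical quantiles. Floors differ between these sets, except that the ILN and jejunum at 12 h share one with 19.0 and 24.6 percent of values at it. Each set was taken as normalized apart, and levels are not compared between organs. Effects are contrasted between times only as differences from the vehicle of the same time.

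Of 45141 probe sets, 104 were controls, 28898 had 1 gene, 551 had several and 15588 had no gene in the sources used here. Those with 1 gene gave 17097 genes, each tested by its probe set of highest mean. Floors lay at 2.12 to 2.25 log2, with 18.5 to 25.5 percent of values at the floor and 4.91 to 10.2 percent of genes at it on every array of a set. The sources give no genome positions.

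In each organ a model with 1 mean per group was fitted by limma 3.58.1 (R 4.3.3, with the data.table package, 1.17.8) with moderated variances. It gave 15 contrasts per organ, 105 in all. They set 4 dosed groups against vehicle at each time, vehicle against naive at 12 h, dosed groups against each other over both times, and the effects of the higher dose and MEF at 12 h against 6 h. P values are 2-sided and Benjamini-Hochberg adjusted within a contrast, and a gene is called below 0.05. Camera, of limma, tested 33 of 34 fixed gene lists with an estimated correlation, adjusted over the lists of a contrast. Adipocyte markers had too few measured genes. Among them were NRF2 target genes, heat shock genes, immediate early genes, zinc response genes, ATF4 stress response genes, interferon response genes, NK cell markers, glucocorticoid response genes, inflammatory NF-kB genes and p53 target genes, and the others are named with their results under other observations. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.

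Named genes followed a rule. For the higher dose and for MEF against vehicle, and between dosed groups, these are the 3 highest and 3 lowest called genes whose mean is above the median of the organ. Up to 4 called members of a list may be named per contrast, and Nqo1, Gclc, Hmox1, Akr1b8, Osgin1, Mt1, Mt2 and Hcar2 in any contrast. Mt2 was not tested. Sex-linked and predicted genes are left out. Tra2b, Hoxb6 and Hoxb9 were chosen after their values had been seen where the rule does not name them.

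Alternatives were a further quantile normalization, dim genes (below the median of the organ) left out, trend and robust variance, a fit of only the groups compared, leaving out each array of groups of up to 5, a preset correlation of 0.01 and the mean of all probe sets of a gene. Added after the data had been seen were a line and a curve at each time for the place of an animal number in runs of 12, contrasts within spans of 4 places holding at least 2 arrays of each group, and the leaving out of kidney 12 h higher-dose replicate 24, of jejunum arrays with a mean Hoxb6 and Hoxb9 level above 6 and of spleen arrays with acinar markers 2 above the lowest array of that time or Alb above 8 log2. Arrays were split into other groups of the same sizes 100 times per contrast, the real split included.

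The steps were tested on simulated data with 50 changed genes per fold size. On a kidney design for the higher dose at 6 h, 66, 94, 98 and 100 percent were recovered at folds of 1.25, 1.5, 2 and 4, with 9 false among 188 calls. With a place gradient added 34 of 217 were false, and 11 of 188 with the covariate. An ILN design for MEF at 12 h gave 52, 88, 94 and 100 percent, with 13 of 180 false. There the gradient gave 6 of 169 false and the covariate, not lowering them, 9 of 170. A raised list was called and 0 of 34 unchanged lists. In the data 4574 of 8548 kidney genes related to place, so false shares may differ.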

Results

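Gene expression was measured on 550 oligonucleotide arrays of RNA from 7 organs of C57BL/6 mice, collected 6 or 12 h after a single dose. Dosed mice received dimethyl fumarate (DMF, the dimethyl ester of fumaric acid) at a lower dose of 100 mg/kg or a higher dose of 179.2 mg/kg, or monoethyl fumarate (MEF) as mixed calcium, magnesium and zinc salts at 79.2 mg/kg. A further group (DMF+MEF) received DMF at its lower dose and the MEF salts per the sample titles, although its source names give the DMF dose alone. The comparison group was given the hydroxypropyl methylcellulose vehicle. Undosed (naive) mice were added at 12 h. The organs were kidney (77 arrays, as labelled, though the series description omits it), jejunum (76), mesenteric lymph node (MLN, 88), inguinal lymph node (ILN, 73), spleen (72), brain (86) and whole blood (78), and the 77 groups held 3 to 8 arrays each. Groups of fewer than 6 arrays were those of the jejunum at 6 h with DMF 100 mg/kg (4), MEF salts (5) and DMF+MEF (5), the kidney at 12 h with DMF+MEF (4), the spleen with DMF+MEF (4 at each time) and naive (3). The others were the ILN at 12 h with vehicle (4) and MEF salts (5), and naive blood (5). Tests covered 17097 genes by 1 probe set each. Where 4 values are given for the dosed groups, their order is the lower dose, the higher dose (of DMF), MEF and DMF+MEF. A called gene passed limma's test after Benjamini-Hochberg adjustment (FDR, the adjusted p) within its contrast, unadjusted counts are those of p below 0.05 before it, lists were tested by camera, errors of log2 changes are standard errors of the model, and errors of log2 levels are SD.

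Splicing regulator Tra2b showed a gradient along the animal numbers. Its level fell along successive runs of 12 animal numbers in each of the 7 organs, for example from 7.97 ± 0.23 (n = 16) at places 1 to 4 to 7.10 ± 0.36 (n = 16) at places 5 to 8 and 6.04 ± 0.69 (n = 16) at places 9 to 12 in the MLN at 12 h. Vehicle and MEF animals held places 1 to 8, the higher DMF dose and naive animals places 5 to 12, and the lower DMF dose and DMF+MEF places 1 to 4 and 9 to 12. Counts of called genes are therefore given also with place, meaning place as a covariate in the fit. Counts within shared places use only the spans of 4 places with at least 2 arrays of each group, so fewer arrays, and some contrasts had too few. Fits of only the groups compared (the groups alone) rest their spread on fewer arrays.

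**Figure D1:**
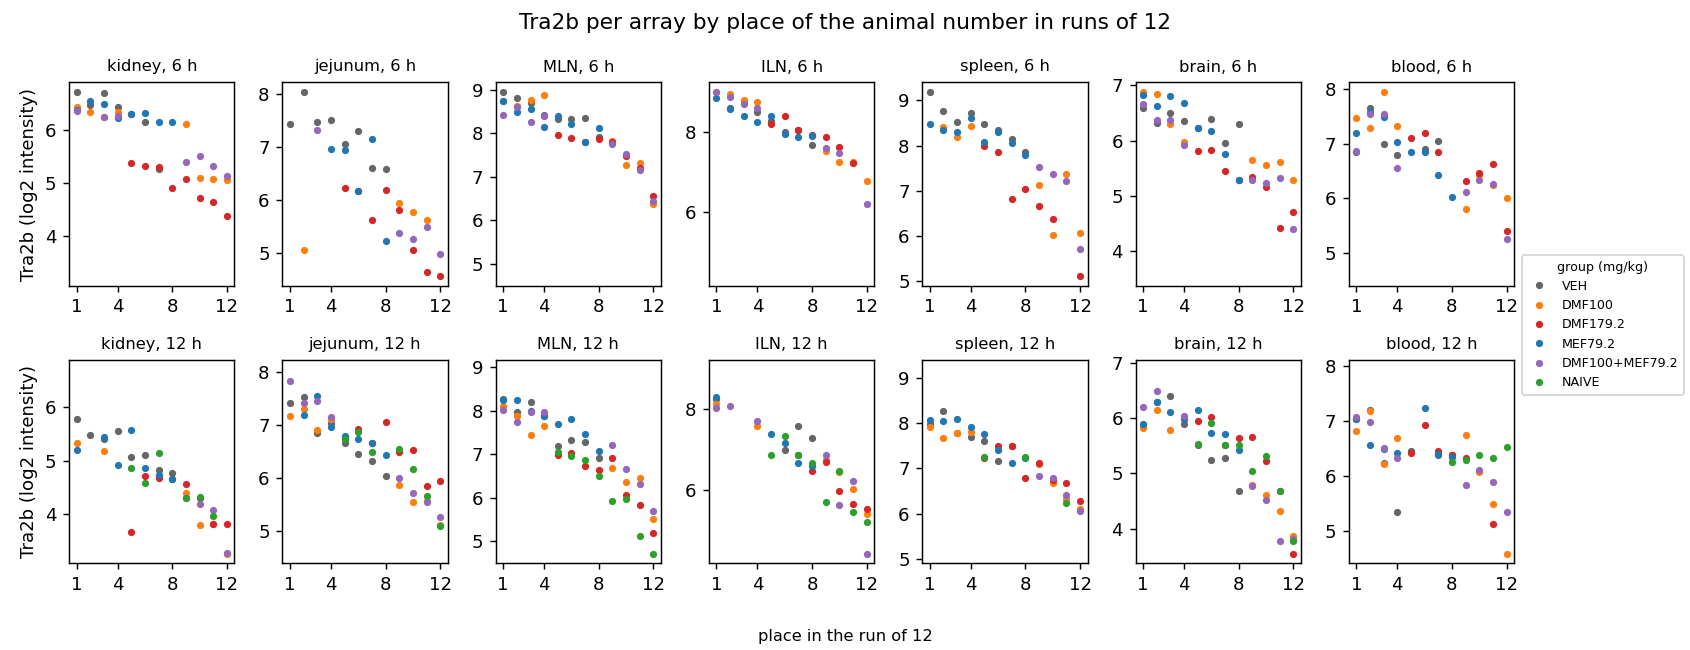
Log2 level of the splicing regulator Tra2b on each array (vertical axis, scaled per organ) against the place of the animal number in runs of 12 (horizontal axis), per organ and time, with points coloured by group. In the MLN at 12 h the mean fell from 7.97 at places 1 to 4 to 6.04 at places 9 to 12.

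In the kidney, targets of NRF2, the transcription factor of the electrophile and oxidative stress response, rose with every dosed group. At 6 h, 20 of the 21 measured members were called higher in each of the 4 groups, also 20 each adjusted over the list alone (by list). Their median log2 changes were 0.71, 0.96, 0.86 and 1.03 (camera, FDR = 9.87e-15, 2.98e-09, 7.81e-16 and 2.24e-13). Carbonyl reductase gene Cbr3 led at 6 h, with log2 changes of 3.93 ± 0.13, 4.30 ± 0.13, 4.41 ± 0.13 and 4.68 ± 0.13. For the higher dose its level was 9.76 ± 0.23 (n = 8) against 5.46 ± 0.20 (n = 7) with vehicle, a 19.7-fold change (FDR = 1.63e-39), and 4.18 on the log2 scale within the shared places. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, rose by 2.35 ± 0.20, 3.47 ± 0.20, 3.67 ± 0.20 and 4.16 ± 0.21.

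The quinone reductase gene Nqo1 rose at 6 h by 1.37, 1.49, 1.41 and 1.63, each ± 0.08. Pgd, of the pentose phosphate pathway, rose by 1.83 ± 0.08 with the higher dose and 1.54 ± 0.08 with MEF, and Gclc, of glutathione synthesis, by 0.99 ± 0.11 and 1.33 ± 0.11. Akr1b8, an aldo-keto reductase gene, rose by 0.96 ± 0.14 and 0.77 ± 0.14, and Osgin1 by 1.03 ± 0.09 and 0.60 ± 0.09. Among 4 measured zinc response genes, 2 were called higher with the lower dose (FDR = 0.00847), with MEF (4.78e-05) and with DMF+MEF (0.00552), where 1 was called lower. The same counts held by list. The metallothionein gene Mt1 rose by 0.49 ± 0.06, 0.86 ± 0.06, 0.81 ± 0.06 and 1.10 ± 0.06. The zinc exporter gene Slc30a1 rose by 0.38 ± 0.04 with MEF and 0.44 ± 0.04 with DMF+MEF. Heat shock genes rose with MEF in 3 of 8 (4 by list, FDR = 0.0123). With the higher dose Chac1, of glutathione breakdown, rose by 1.38 ± 0.21, the clock gene Per1 by 1.59 ± 0.26, and the neutrophil genes S100a8 and S100a9 by 1.34 ± 0.24 and 0.97 ± 0.28. Gstm3, a glutathione transferase gene, rose by 2.21 ± 0.17 from 2.94 ± 0.14, near the floor of 2.16, and Atf3 and Asns by 0.78 ± 0.19 and 0.76 ± 0.16. Lowest were Snx29 at -1.40 ± 0.14, Rbm12b1 at -1.15 ± 0.20 and Mia3 at -1.08 ± 0.22, which came to -1.18, -0.69 and -0.61 with that covariate. With MEF the lowest were Mfsd2a at -1.08 ± 0.14, Napsa at -0.79 ± 0.10 and the amino acid transporter gene Slc6a15 at -0.78 ± 0.22.

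Kidney counts at 6 h were 695 called genes (384 higher, 311 lower), 4267 (2559, 1708), 1008 (498, 510) and 2253 (1069, 1184). With place they were 709, 3669, 1309 and 2336, within shared places 523, 1255, 1308 and 1553 and with the groups alone 616, 3902, 1117 and 1659.

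At 12 h the NRF2 targets of the kidney were still higher, in 12, 16, 14 and 18 of 21. By list they numbered 16, 17, 14 and 20 (FDR = 1.02e-08, 4.44e-10, 1.97e-05 and 1.25e-09). Cbr3 was 3.78, 7.98, 7.02 and 12.7 times as high as with vehicle. Nqo1 rose by 1.02, 1.45, 1.30 and 1.75. Hmox1 rose with the higher dose by 1.03 ± 0.20 and with DMF+MEF by 1.08 ± 0.24. Its 0.52 ± 0.21 with the lower dose and 0.43 ± 0.20 with MEF were not called (FDR = 0.28 and 0.14). Genes of the ATF4 stress response, the program of amino acid shortage and endoplasmic reticulum stress, rose in 10 of 12 with the higher dose (FDR = 5.66e-06) and in 9 of 12 with DMF+MEF (4.78e-06). By list both had 10. They included Chac1 (1.28 ± 0.20 and 1.88 ± 0.24), Atf3 (0.89 ± 0.19 and 1.55 ± 0.23) and the pseudokinase gene Trib3 (0.81 ± 0.13 and 1.57 ± 0.16). With DMF+MEF Ddit3, which encodes the stress transcription factor CHOP, rose by 0.96 ± 0.10. With the higher dose the asparagine synthetase gene Asns rose by 0.71 ± 0.15 and the cell cycle inhibitor gene Cdkn1a by 0.79 ± 0.17. Higher-dose replicate 24 stood above its group in Atf3, Trib3 and Asns. Without it, a fit chosen after the data had been seen, these genes were at 0.61, 0.60 and 0.63 and still called, as was the list (FDR = 3.01e-05), with 1495 called genes in all. Aldh1a7 rose by 1.43 ± 0.14 with the higher dose and 1.33 ± 0.14 with MEF, and Hdc, which encodes the enzyme that makes histamine, fell by 1.22 ± 0.24 and 1.18 ± 0.25. The higher dose lowered Ccn1 (-1.07 ± 0.20) and Foxq1 (-0.98 ± 0.15). MEF lowered the bile acid transporter gene Slc10a2 (-1.09 ± 0.13) and the vitamin D hydroxylase gene Cyp24a1 (-0.97 ± 0.30), as well as the clock genes Cry1 (-0.65 ± 0.13) and Npas2 (-0.59 ± 0.21).

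Called genes in the kidney at 12 h numbered 236 (131 higher, 105 lower), 1240 (776, 464), 2991 (1203, 1788) and 1884 (927, 957). With place they numbered 246, 1226, 3459 and 2212, and within shared places 80, 453 and 3246, with too few arrays for DMF+MEF. The groups alone gave 57, 742, 2702 and 966. Without replicate 36 DMF+MEF gave 1237.

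**Figure D2:**
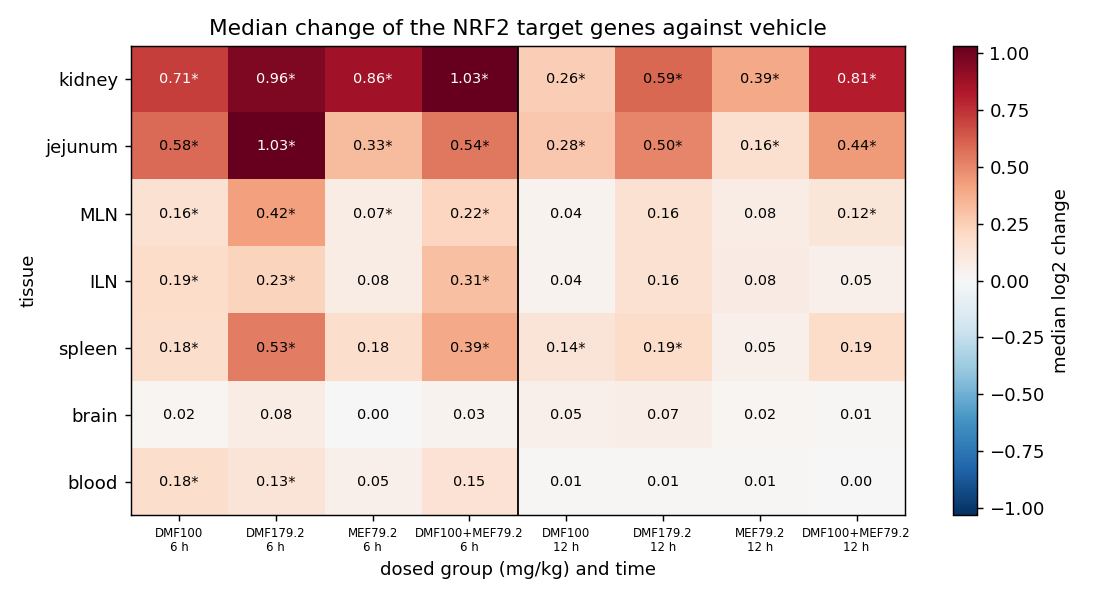
Median log2 change against vehicle of the 21 measured NRF2 target genes, per organ (vertical axis) and per dosed group and time (horizontal axis), with colour and number giving the median. An asterisk marks a camera call, and the medians ran from 0.00 in the blood to 1.03 in the kidney and 1.03 in the jejunum.

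In the jejunum Cbr3 rose at 6 h by 4.64 ± 0.39 with the lower dose, 6.25 ± 0.32 with the higher, 1.47 ± 0.36 with MEF and 5.23 ± 0.36 with DMF+MEF. For the higher dose this was a 76.1-fold change from 4.13 ± 0.32 to 10.38 ± 0.37 (n = 8 and 8, FDR = 2.32e-25). Akr1b8 rose by 4.40 ± 0.31, 4.85 ± 0.25, 1.86 ± 0.29 and 4.36 ± 0.29, and Nqo1 by 1.60, 1.91, 0.71 and 1.64. With the higher dose the carboxylesterase gene Ces1g rose by 3.84 ± 0.33, Gclc by 2.28 ± 0.13 and Per1 by 1.43 ± 0.29, whereas Hmox1, at 0.50 ± 0.17, was not called (FDR = 0.0616). Lowest with that dose were Tra2b (-1.71 ± 0.34), Apob, which encodes an apolipoprotein of chylomicrons (-1.28 ± 0.34), and the glycolysis regulator gene Pfkfb3 (-1.09 ± 0.29). They were at -1.11, -0.60 and -0.81 with place, where Pfkfb3 was no longer called (FDR = 0.132). With MEF the aldo-keto reductase gene Akr1c19 rose by 1.27 ± 0.23, and Ccnjl, the immediate early response gene Ier5 and Myct1 were lowest at -0.74 ± 0.19, -0.71 ± 0.18 and -0.61 ± 0.17. Cbr3, Ccnjl and Myct1 lost their calls with MEF without replicate 78, 81 or 82, and Ier5 without 80, 81 or 82.

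NRF2 targets of the jejunum were called higher at 6 h in 14, 19, 4 and 16 of 21. By list they numbered 16, 20, 14 and 18, with 1 lower with MEF. Camera gave FDR = 3.58e-08, 1.97e-12, 0.0192 and 7.77e-08. The MEF call ended without dim genes (FDR = 0.337). All genes called numbered 447 (302 higher, 145 lower), 1473 (958, 515), 204 (151, 53) and 1123 (719, 404), or 637, 1316, 278 and 433 with place and 23, 944, 21 and 273 with the groups alone. Within shared places the higher dose gave 372 and MEF 40, with too few arrays for the other groups. The lower dose gave 95 without replicate 64 and 824 without 60. MEF gave 23 without replicate 82 and 430 without 79, and DMF+MEF gave 610 without replicate 86 and 1670 without 89.

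At 12 h, Akr1b8 of the jejunum remained called, at 2.87 ± 0.25, 4.42 ± 0.25, 2.13 ± 0.26 and 4.08 ± 0.25, as did Nqo1 at 1.06, 1.64, 0.66 and 1.53, each ± 0.10. There NRF2 targets were higher in 9, 13, 4 and 12 of 21, or 10, 16, 6 and 15 by list (FDR = 4.59e-05, 3.24e-08, 0.0407 and 1.26e-08). Vehicle replicates 5, 6 and 7 carried Hox genes of the distal intestine, with a mean Hoxb6 and Hoxb9 level of 7.44 to 7.90 against 3.01 to 3.99 in the other 5 vehicle arrays. Replicate 15 of the lower dose reached 6.27. Without the 4 arrays with Hox genes, chosen after the data had been seen, the NRF2 list was called with all groups but MEF (FDR = 0.309, and 0.109 without dim genes and 0.0532 after a further quantile normalization). Cbr3 rose with the higher dose by 3.91 ± 0.32. The sugar sensor gene Slc5a4b, at 3.21 ± 0.46 with the higher dose, came to 1.42 without them. Gcnt1 and the carbonic anhydrase gene Car12, at -1.24 ± 0.39 and -1.03 ± 0.33, came to 0.05 and -0.14 and were not called (FDR = 1 for both). The leading MEF genes did so too. Dnase1, the glucuronosyltransferase gene Ugt2a3 and the proximal intestine regulator Gata4 went from 2.66 ± 0.64, 2.49 ± 0.63 and 2.34 ± 0.51 to 0.29, 0.46 and 0.45, with FDR = 0.924, 0.924 and 0.758. Msmo1, Hoxb3 and Slc30a1, lowest with MEF at -0.80, -0.75 and -0.71, came to -0.26, -0.12 and -0.37, none called. Ifit1bl2 fell with the higher dose by 1.00 ± 0.23 and missed the call with place (FDR = 0.0562).

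The jejunum at 12 h gave 108 called genes (76 higher, 32 lower), 1266 (810, 456), 139 (94, 45) and 590 (311, 279). Without the 4 arrays they numbered 37, 270, 5 and 76. With place they numbered 36, 1313, 258 and 513, within shared places 24, 1562, 370 and 44 and with the groups alone 15, 574, 1 and 98.

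In the MLN, which drains the gut, Nqo1 rose at 6 h by 1.46 ± 0.16 with the lower dose, 2.60 ± 0.16 with the higher, 0.81 ± 0.16 with MEF and 1.97 ± 0.16 with DMF+MEF. The higher dose, 6.06-fold, took its level from 6.59 ± 0.27 to 9.19 ± 0.17 (n = 8 and 8, FDR = 6.44e-23). The same dose raised the aldehyde oxidase gene Aox1 by 1.31 ± 0.23 and Slc40a1, which encodes the iron exporter ferroportin, by 0.99 ± 0.13. Its lowest genes, the interferon-inducible Ifi203 (-0.43 ± 0.10), the BMP antagonist gene Grem1 (-0.40 ± 0.10) and Neurl4 (-0.38 ± 0.09), were no longer called with place (FDR = 0.11, 0.0845 and 0.0879). NRF2 targets were higher in 2, 11, 1 and 8 of 21, and 8, 13, 2 and 10 by list (FDR = 1.08e-06, 1.23e-14, 0.000397 and 1.39e-09). All called genes numbered 4 (4 higher, 0 lower), 67 (54, 13), 1 (Nqo1) and 31 (24, 7). Place as a covariate gave 3, 47, 1 and 17, and shared places 7, 19, 1 and 10, and with the groups alone 1, 80, 0 and 9 (limma, 505 unadjusted for 0).

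At 12 h Nqo1 of the MLN changed by 0.79 ± 0.16, 1.44 ± 0.16 and 1.19 ± 0.16 with the 3 DMF groups. Its 0.27 ± 0.16 with MEF was not called (FDR = 0.49). For the higher dose the chaperone gene Dnajb1 fell by 0.67 ± 0.09 and the immediate early gene Fos by 0.75 ± 0.20. Heat shock genes were lower in 3 of 8 with that dose and 4 of 8 with DMF+MEF, 4 each by list (FDR = 0.00549 and 0.00548). The stress-induced chaperone gene Hspa1b changed by -0.81 ± 0.21 with DMF+MEF and -0.80 ± 0.21 with MEF. Immediate early genes were lower in 0, 5 and 2 of 11 with the 3 DMF groups, or 2, 6 and 5 by list (FDR = 0.0318, 0.00549 and 0.00548). With place the first of these calls ended (FDR = 0.205). NK cell markers were higher with DMF+MEF in 1 of 6, or 4 by list (FDR = 0.0257). Without dim genes the heat shock calls ended (0.0564 and 0.0939), as did the immediate early calls with the lower dose and DMF+MEF (0.0658 and 0.0939) and the NK call (0.0939). NRF2 targets were called as a list with DMF+MEF alone, 4 of 21 higher and 9 by list (0.00548). They numbered 2, 8 and 0 higher with the lower dose, the higher dose (1 lower) and MEF, or 2, 10 (2 lower) and 2 by list (0.46, 0.109 and 0.28). The cyclin gene Ccnd3 and Cnnm3 led beside Nqo1 with the higher dose (0.93 ± 0.15 and 0.90 ± 0.12). Tra2b, Zfp800 and Rbm12b1, its lowest genes at -1.21, -1.05 and -1.04, came to -0.39, -0.50 and -0.45 with place, where Rbm12b1 was not called (FDR = 0.0719). The highest with MEF were the DNA repair gene Abraxas1 at 0.40 ± 0.08, Zxdc at 0.37 ± 0.08 and Golph3l at 0.27 ± 0.07. The lowest, after Hspa1b, were Tenm3 at -0.65 ± 0.13 and the transcription factor gene Cebpd at -0.54 ± 0.12. Called genes numbered 14 (10 higher, 4 lower), 2364 (1536, 828), 103 (19, 84) and 725 (311, 414). Place turned these into 56, 1808, 244 and 1181, and within shared places 21, 620, 243 and 302, and with the groups alone 0, 916, 6 and 78 (limma, 976 unadjusted for 0).

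In the ILN at 6 h Nqo1 rose by 0.94 ± 0.15, 1.76 ± 0.15 and 1.39 ± 0.15 with the 3 DMF groups. With MEF it was at 0.13 ± 0.15 and not called (FDR = 1). The higher dose raised Aox1 by 1.56 ± 0.20 and Slc40a1 by 1.02 ± 0.18, and Zfp110 fell by 0.27 ± 0.06. NRF2 targets were higher in 3, 8 and 8 of 21 with the 3 DMF groups and 0 with MEF, or 9, 11, 10 and 0 by list (FDR = 8.52e-08, 2.77e-12, 4.32e-08 and 0.186). Glucocorticoid response genes rose with DMF+MEF in 1 of 8, or 3 by list (FDR = 0.027), a call that ended without dim genes (FDR = 0.215). Called genes numbered 5 (5 higher, 0 lower), 40 (29, 11), 1 (0, 1) and 74 (35, 39). With place these were 3, 91, 6 and 166, within shared places 25, 15, 9 and 12 and with the groups alone 0, 27, 0 and 87 (limma, 981 and 1517 unadjusted for 0).

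In the ILN at 12 h the protease genes Cpa3, Cma1 and Mcpt4 rose by 1.95 ± 0.39, 1.77 ± 0.37 and 1.71 ± 0.39 with the higher dose and by 1.82 ± 0.40, 1.82 ± 0.38 and 1.56 ± 0.40 with MEF. Without vehicle replicate 7, Mcpt4 came to 0.90 with the higher dose and Cma1, Cpa3 and Mcpt4 to 1.06, 1.14 and 0.75 with MEF, none of which was called. The antiviral genes Oas3, Oasl1 and Oas2 were lowest with the higher dose, at -1.98 ± 0.55, -1.76 ± 0.48 and -1.47 ± 0.45, and came to -1.26, -1.06 and -0.94, not called, without vehicle replicate 1. The interferon-induced GTPase gene Gbp2, Xrn1 and the chaperone gene Pfdn2 were lowest with MEF at -0.70 ± 0.17, -0.94 ± 0.18 and -0.66 ± 0.18. Gbp2 and Pfdn2 came to -0.32 and -0.38, not called, without the same array. Nqo1 rose by 0.70 ± 0.18, 1.16 ± 0.18 and 0.85 ± 0.18 with the 3 DMF groups, the first and last not called without vehicle replicate 1 (0.53 and 0.68), and was at 0.58 ± 0.19 with MEF, not called (FDR = 0.1). The NRF2 list was not called (FDR = 0.806, 0.492, 0.675 and 0.662), with 2, 5, 1 and 3 members higher, 3, 5, 5 and 3 by list, and 1 lower with the higher dose. Heat shock genes were lower with DMF+MEF in 3 of 8, 4 by list (0.0117). Called genes numbered 217 (148 higher, 69 lower), 2110 (1349, 761), 179 (69, 110) and 603 (305, 298). They were 497, 1161, 624 and 1205 with place. Shared places gave 281 with the higher dose and 127 with MEF, with too few arrays for the other groups. The groups alone gave 0, 157, 0 and 0 (limma, 1091, 936 and 1162 unadjusted for 0). Without vehicle replicate 1 they were 44, 297, 75 and 170, and without vehicle replicate 8 they were 734, 2677, 658 and 982.

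**Figure D3:**
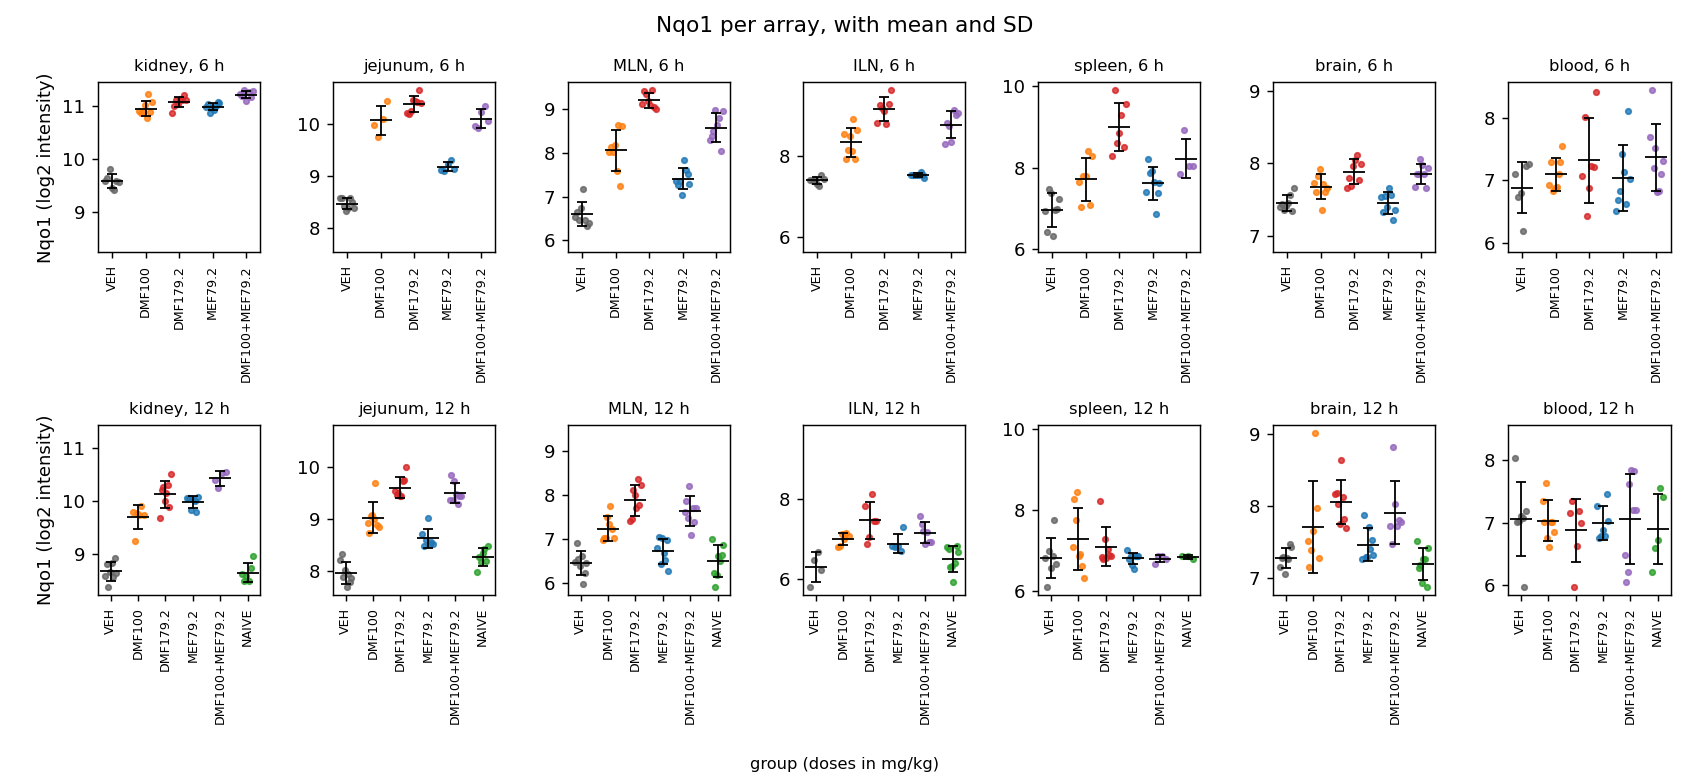
Log2 level of the quinone reductase gene Nqo1 on each array (vertical axis, scaled per organ) by group (horizontal axis), per organ and time. Points are arrays, horizontal lines group means and bars SD, and in the MLN at 6 h the mean was 9.19 ± 0.17 with DMF 179.2 mg/kg against 6.59 ± 0.27 with vehicle.

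In the spleen at 6 h, Nqo1 rose by 2.05 ± 0.25 with the higher dose and 1.26 ± 0.30 with DMF+MEF. Its 0.76 ± 0.25 with the lower dose and 0.65 ± 0.24 with MEF were not called (FDR = 0.219 and 0.118). Aox1 rose by 1.92 ± 0.14 with the higher dose and 0.75 ± 0.14 with MEF, and Gclm, of glutathione synthesis, by 1.04 ± 0.28 and 0.90 ± 0.27. Higher with the higher dose were also the neutrophil genes Csf3r (1.20 ± 0.24) and S100a8 (0.69 ± 0.16), Asns (1.54 ± 0.41). So were the red cell genes Kel (2.38 ± 0.77) and Alas2 (1.11 ± 0.36) with Ypel4 (1.98 ± 0.67). MEF raised the transcription factor gene Klf11 by 0.65 ± 0.14, and Hspa1b, Prr15 and Lrif1 fell by 0.99 ± 0.20, 0.75 ± 0.22 and 0.65 ± 0.15. Tra2b, Rbm12b1 and the nuclear receptor gene Nr2c2 were lowest with the higher dose at -1.66, -1.36 and -1.30, or -0.88, -0.83 and -0.77 with place. Markers of the pancreatic acinar cell stood high on 17 spleen arrays and albumin on 2 more (6 h DMF+MEF replicate 85 and naive replicate 47). The 6 h vehicle group held 4 of 8 arrays with acinar RNA against 0 of 7 with the higher dose, 1 of 8 with MEF, 2 of 7 with the lower dose and 1 of 4 with DMF+MEF. Without these 19 arrays, left out after the data had been seen, Nqo1, Aox1 and Csf3r were still called with the higher dose. Nqo1 with DMF+MEF (0.96) was not (FDR = 0.266), nor without DMF+MEF replicate 84 (1.02). Gclm (0.78), S100a8 (0.51), Kel (1.96), Alas2 (0.69) and Ypel4 (1.67) were not (FDR = 0.101, 0.0804, 0.153, 0.347 and 0.203), and with place Asns was not (FDR = 0.0504). None of the 6 MEF genes was called without them, with changes from -1.03 to 0.64. NRF2 targets were higher in 3, 14, 5 and 9 of 21 with the 4 groups (1 lower with the higher dose). By list 10, 15, 8 and 14 were higher and 0, 2, 2 and 2 lower (FDR = 0.00282, 0.00532, 0.328 and 0.000252). Without the 19 arrays these FDR were 0.0874, 0.037, 0.333 and 0.154.

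Spleen counts at 6 h were 25 called genes (17 higher, 8 lower), 3927 (2833, 1094), 598 (168, 430) and 681 (457, 224). They were 10, 2101, 4 and 170 without the 19 arrays, 11, 2394, 1091 and 266 with place, and 26, 411 and 864 within shared places, with too few arrays for DMF+MEF. The groups alone gave 0, 2949, 683 and 98 (limma, 1712 unadjusted for 0). Without DMF+MEF replicate 86 that group gave 396.

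In the spleen at 12 h the glutathione transferase gene Gstm1 rose by 1.12 ± 0.10 with the higher dose and 0.45 ± 0.10 with MEF, Gstm2 by 0.70 ± 0.10 and Aox1 by 0.87 ± 0.14 with the higher dose. Nqo1, at 0.46 ± 0.25, 0.27 ± 0.25, -0.01 ± 0.25 and -0.03 ± 0.30, was not called (FDR = 0.806, 0.813, 1 and 1). The chaperone genes Dnajb1 and Dnaja1 fell by 0.47 ± 0.08 and 0.37 ± 0.07 with the higher dose, along with Nab2 (-0.38 ± 0.09), and Hspa1b fell by 0.95 ± 0.26 with DMF+MEF. Without the 19 arrays Dnaja1, Nab2 and Hspa1b were not called (FDR = 0.0589, 0.102 and 0.0868), and Hspa1b lost its call also without DMF+MEF replicate 33, 34 or 35. Heat shock genes were lower in 1 of 8 with the higher dose and 5 with DMF+MEF, or 3 and 5 by list (FDR = 0.00606 and 0.00017). The first of these calls ended without the 19 arrays (0.0707). NRF2 targets were higher in 1 with the lower dose and 3 with the higher (2 and 8, 1 lower, by list), with FDR = 0.0119 and 0.0111. These were 0.0589 and 0.0707 without the 19 arrays and 0.0776 and 0.0911 with place. They were not called with MEF or DMF+MEF (FDR = 0.972 and 0.415). Immediate early genes were called lower with the lower dose (0 of 11, 2 by list, FDR = 0.0119, and 0.0643 without the 19 arrays and 0.112 without dim genes). The next highest with MEF were Nol9 and Mindy1 (0.42 ± 0.10 and 0.42 ± 0.10). Lowest were the cell division gene Cep55 (-0.58 ± 0.15), Sec24a (-0.56 ± 0.11) and Ell2 (-0.55 ± 0.13). None of these 5 was called without the 19 arrays. Called genes numbered 3 (1 higher, 2 lower), 81 (63, 18), 158 (71, 87) and 574 (479, 95). They were 6, 50, 20 and 115 without the 19 arrays and 1, 55, 466 and 563 with place. Within shared places they were 22, 9 and 249, with too few arrays for DMF+MEF. The groups alone gave 0, 5, 52 and 188 (limma, 777 unadjusted for 0). Without DMF+MEF replicate 35, 36 or 34 that group gave 247, 266 or 324.

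In the brain the higher dose lowered some immediate early genes and raised Nqo1. At 6 h the transcription factor genes Egr2 and Fos fell by 1.26 ± 0.24 and 0.86 ± 0.25, Aox1 rose by 1.09 ± 0.11 and Nqo1 by 0.43 ± 0.14. At 12 h the synaptic plasticity gene Arc, the phosphatase gene Dusp1 and the nuclear receptor gene Nr4a1 fell by 1.36 ± 0.29, 0.94 ± 0.14 and 0.90 ± 0.21. Nqo1, the kinase gene Lrrk2 and the clock gene Per2 rose by 0.77 ± 0.14, 0.70 ± 0.13 and 0.62 ± 0.12. With MEF Egr2 fell by 1.16 ± 0.24 at 6 h, and Nr4a1 and Dusp1 by 1.15 ± 0.21 and 0.67 ± 0.14 at 12 h. Nqo1 rose at 12 h with DMF+MEF by 0.63 ± 0.14 and was not called with the lower dose (0.23 ± 0.14 and 0.43 ± 0.14 at 6 and 12 h), MEF (0.00 ± 0.14 and 0.18 ± 0.14) or, at 6 h, DMF+MEF (0.41 ± 0.14). Hmox1 was not called with the higher dose at 12 h (0.03 ± 0.12).

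Other brain genes changed too. At 6 h with the higher dose Polrmt and Abhd4 rose by 0.76 ± 0.18 and 0.59 ± 0.14 and Rbm12b1 fell by 0.91 ± 0.27. Fitted with place none of these, nor Nqo1, was called (FDR = 0.0663, 0.0749, 0.157 and 0.231). MEF raised Fam81a (0.48 ± 0.08), Edil3 (0.35 ± 0.08) and Eif4a1 (0.22 ± 0.03) at 6 h with Ddx51 (-0.27 ± 0.06) and Wdr5 (-0.22 ± 0.04) lower. At 12 h it raised Schip1 (0.33 ± 0.06) and Nmnat2 (0.20 ± 0.05) with Armh4 (-0.38 ± 0.08) lower. The NRF2 list was not called in any dosed group, with FDR = 0.901, 0.644, 0.989 and 0.622 at 6 h and 0.287, 0.215, 0.68 and 0.76 at 12 h. Yet 5 and 4 of 21 were called higher with the higher dose (8 and 4 by list). In the fit with place the higher dose at 12 h was called (FDR = 0.00684). Immediate early genes as a list were not called with the higher dose at 6 h (3 of 11 lower, 3 by list, FDR = 0.644) or 12 h (5 and 7, 0.0568). They were lower with MEF at 12 h in 2 of 11, or 7 by list (FDR = 0.0408, and 0.0997 with place, 0.0511 without dim genes and 0.053 after quantile normalization). Lower at 12 h were heat shock genes with MEF (0 of 8, 1 by list) and DMF+MEF (1, 3), with FDR = 0.02 and 0.00216. Neither was called with place (0.0897 and 0.0821) or dim genes left out (0.208 and 0.119). Called genes at 6 h numbered 2 (1 higher, 1 lower), 1231 (959, 272), 21 (7, 14) and 18 (11, 7). They were 3, 124, 36 and 14 with place and 27, 12, 32 and 36 within shared places, and with the groups alone 1, 1453, 0 and 12 (limma, 983 unadjusted for 0). At 12 h they numbered 4 (1, 3), 224 (102, 122), 15 (4, 11) and 248 (101, 147). They were 18, 245, 119 and 552 with place and 115, 309, 90 and 37 within shared places (2, 78, 15 and 10 of them also called above), and with the groups alone 0, 41, 3 and 1 (limma, 741 unadjusted for 0).

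In whole blood at 6 h with the higher dose the neutrophil collagenase gene Mmp8 rose by 1.74 ± 0.34, the iron exporter gene Slc40a1 by 1.54 ± 0.33 and Piwil2 by 1.49 ± 0.34. Hmox1, at 1.01 ± 0.32, was not called (FDR = 0.319). At 12 h that dose raised Zkscan8, Adgrl1 and Rnf103 by 1.03 ± 0.17, 0.80 ± 0.18 and 0.66 ± 0.14. Dnaja1, Slfn8, Eme2 and Dnajb1 fell by 0.65 ± 0.14, 0.61 ± 0.14, 0.59 ± 0.14 and 0.58 ± 0.14, while Nqo1 was called in 0 of the 4 groups at 6 h (0.21, 0.43, 0.15 and 0.48) and 12 h (-0.03, -0.18, -0.07 and 0.00). With place Adgrl1, Rnf103, Dnaja1, Eme2 and Dnajb1 were not called (FDR = 0.115, 0.0685, 0.0708, 0.0685 and 0.115). NRF2 targets were called as a list at 6 h with the lower dose (0 of 21, 0 by list, FDR = 0.0418, and 0.0774 with place and 0.0817 without dim genes). They were called also with the higher dose (1 of 21, 5 by list, FDR = 0.00852). They were not with MEF or DMF+MEF (0.524 and 0.0871) or at 12 h (0.709, 0.61, 0.903 and 0.815). Interferon response genes were called lower as a list with the higher dose at 12 h (0 of 9, 7 by list, median -0.57, FDR = 0.024). At 6 h limma called 0, 12 (12 higher), 0 and 1 genes with the 4 groups (1102 and 973 unadjusted for 0). With place they were 0, 13, 0 and 11. Within shared places they were 0, 436, 166 and 16 (0, 5, 0 and 1 of them also called above), and with the groups alone 1, 3, 0 and 0 (limma, 362 and 857 unadjusted for 0). At 12 h the groups gave 6 (3 higher, 3 lower), 55 (45, 10), 1 (0, 1) and 37 (28, 9). They were 6, 6, 1 and 34 with place, and 39, 24, 1 and 9 within shared places, and with the groups alone 0, 0, 0 and 0 (limma, 1205, 987, 736 and 822 unadjusted for 0).

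Vehicle and naive mice were compared at 12 h as the background of dosing. In the brain the immediate early genes Arc, Nr4a1, Egr2 and Fos were higher with vehicle by 1.64 ± 0.29, 1.52 ± 0.21, 1.42 ± 0.24 and 1.35 ± 0.25. Of this list 6 of 11 genes were called, 8 by list (FDR = 0.00361, and 0.0779 with place). In the MLN 6 of 11 were called, 7 by list (0.0149, and 0.0597 with place), with Fos at 0.83 ± 0.20. Heat shock genes were higher with vehicle in 5 of 8 in the MLN, 4 of 8 in the ILN and 5 of 8 in the spleen. By list they numbered 5, 4 and 6 (FDR = 0.00131, 0.027 and 0.00557, the last 0.055 without the 19 arrays). Hspa1b rose by 1.12 ± 0.21, 1.73 ± 0.28 and 0.77 ± 0.14 in the MLN, spleen and kidney. Dnajb1 rose by 0.72 ± 0.09, 0.61 ± 0.10, 0.50 ± 0.11 and 0.66 ± 0.15 in the MLN, ILN, spleen and blood, the last not called with place (0.456). In the brain the heat shock list was called with 0 of 8 members called and 0 by list (0.0393, and 0.4 with place and 0.412 without dim genes). Targets of p53 rose in the MLN in 5 of 9, also 5 by list (0.0042), among them Zmat3 (0.45 ± 0.06) and Eda2r (0.46 ± 0.13). The glucocorticoid-induced gene Tsc22d3 changed by 0.65 ± 0.18. In the kidney the clock genes Npas2 and Cry1 were higher with vehicle by 1.00 ± 0.22 and 0.93 ± 0.14 and Dbp fell by 0.67 ± 0.20. So did the glucocorticoid-induced Zbtb16 (-1.19 ± 0.47, and -0.95 with place, FDR = 0.129). In the ILN Hsp90aa1 was higher by 0.73 ± 0.15, and the chemokine genes Ccl3 and Cxcl10, at 0.91 ± 0.30 and 1.34 ± 0.35, came to 0.04 and 0.51, not called, without vehicle replicate 1. In the jejunum Apoa4, Sqle, Chac1 and Akr1b8, at -2.00, 0.96, -1.86 and -0.97, were not called without the 4 arrays with distal genes (FDR = 0.376, 0.72, 0.262 and 0.31).

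The kidney differed most between vehicle and naive mice, with 7871 called genes (3282 higher, 4589 lower with vehicle), 7849 with place and 6613 within shared places. The MLN gave 4174 (1890, 2284), then 3865 and 1549, and the spleen 3130 (1376, 1754), then 3772 and 2752, with 2927 without the 19 arrays and 1356 without naive replicate 41. The ILN gave 2485 (1049, 1436), then 1975 and 455, but 699 without vehicle replicate 1. The jejunum gave 930 (313, 617), then 1158 and 1551, but 27 without the 4 arrays. The brain gave 437 (190, 247), then 878 and 263, and the blood 46 (11, 35), 10 with place, too few arrays in shared places, and 18 without naive replicate 48. In this order the groups alone gave 6681, 2297, 1079, 303, 97, 397 and 1.

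The 2 esters were compared over both times, DMF at 100 mg/kg against MEF salts at 79.2 mg/kg, doses that differ by mass. In the jejunum Cbr3 was higher with DMF by 1.96 ± 0.27, Akr1b8 by 1.64 ± 0.21, Ces1g by 1.55 ± 0.28 and Nqo1 by 0.65 ± 0.08. There 6 of 21 NRF2 targets were higher, 12 by list (FDR = 0.00111). In the kidney genes lower with DMF included Cbr3 at -0.69 ± 0.09, Hmox1 at -0.61 ± 0.15 and the transcription factor gene Klf11 at -0.75 ± 0.12. The follistatin gene Fst was higher with DMF by 0.62 ± 0.14. There the NRF2 list was not called (0 of 21 higher and 10 lower, 1 and 13 by list, FDR = 0.0865), except with place (0.0374) or after quantile normalization (0.0316). Nqo1 of the kidney, at -0.16 with an unadjusted 95% interval of -0.28 to -0.04, was not called, except with place (-0.21, FDR = 0.0306). Nqo1 was higher with DMF in the MLN by 0.58 ± 0.11. It did not differ by the test in the ILN (95% interval 0.24 to 0.68), spleen (-0.06 to 0.64), brain (0.04 to 0.43) and blood (-0.32 to 0.41). Hspa1b was higher with DMF in the MLN by 0.71 ± 0.15 and the spleen by 0.77 ± 0.15. The heat shock list was called in the MLN (2 of 8 higher, 4 by list, FDR = 0.00333, and 0.162 without dim genes). Sh3d19 and Osbpl3 of the jejunum, lower with DMF at -0.68 and -0.68, were not called with place (FDR = 0.196 and 0.161). Called genes numbered 2276 in the kidney (1474 higher with DMF, 802 lower), 321 in the jejunum (166, 155), 263 in the MLN (199, 64). They numbered 4 in the ILN (4, 0), 1750 in the spleen (1249, 501) and 1 in the brain (1, 0), with 0 by limma in the blood (680 unadjusted). In this order they were 878, 36, 76, 0, 462, 0 and 0 with place, and 35, 12, 34, 25 and 0 within shared places for all but the jejunum and ILN, which had too few arrays. The groups alone gave 2422, 146, 322, 2, 1742, 8 and 1. Without the 19 arrays the spleen gave 881. The jejunum gave 153 without 6 h MEF replicate 82 and 614 without 6 h replicate 64 of the lower dose.

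A dose of 179.2 against 100 mg/kg DMF raised Cbr3 by 2.16 ± 0.25, Ces1g by 1.29 ± 0.26, Akr1b8 by 1.00 ± 0.20 and Nqo1 by 0.45 ± 0.08 in the jejunum. It raised Hmox1 by 0.81 ± 0.14, Cbr3 by 0.72 ± 0.09, Aox1 by 0.57 ± 0.14 and Nqo1 by 0.27 ± 0.06 in the kidney. Nqo1 rose by 0.89 ± 0.11 and 0.64 ± 0.11 in the MLN and ILN. Aox1 was higher in the spleen by 0.49 ± 0.10 (not called without the 19 arrays, FDR = 0.123) and the brain by 0.42 ± 0.08, where Dusp1 was lower (-0.49 ± 0.10, FDR = 0.113 with place). Nqo1 of the spleen did not differ by the test (95% interval 0.20 to 0.90). NRF2 targets were higher in 12 of 21 in the kidney, 8 in the jejunum, 5 in the MLN and 1 in the ILN, or 16, 16, 14 (1 lower) and 7 by list (FDR = 0.000265, 5.11e-08, 1.81e-05 and 0.0049). ATF4 genes were higher in 8 of 12 in the kidney, 9 (and 1 lower) by list (0.000848, and 0.0736 without dim genes). Heat shock genes were lower in 3, 1 and 0 of 8 in the MLN, spleen and ILN, 5, 5 and 1 by list (1.42e-05, 0.00986 and 0.0304, the last 0.117 with place and 0.0516 without dim genes). Immediate early genes were lower in 1 of 11 in the brain, 8 by list (0.0275). Called genes numbered 1016 in the kidney (783 higher, 233 lower), 84 in the jejunum (61, 23), 130 in the MLN (88, 42). They numbered 2 in the ILN (1, 1), 220 in the spleen (180, 40), 92 in the brain (66, 26) and 0 by limma in the blood (606 unadjusted). In this order they were 709, 93, 29, 1, 154, 5 and 0 with place and 584, 58, 31, 7, 18, 141 and 0 (limma, 625 unadjusted for 0) with the groups alone. The spleen gave 1 without the 19 arrays. Shared places gave 631, 51, 2, 5, 54, 83 and 2.

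Adding MEF salts to 100 mg/kg DMF raised Cbr3 of the kidney by 1.25 ± 0.10, Hmox1 by 1.19 ± 0.16, Aldh1a7 by 0.83 ± 0.12 and Nqo1 by 0.50 ± 0.07. It raised Cbr3 of the jejunum by 1.45 ± 0.27 and Nqo1 of the MLN by 0.46 ± 0.11. Nqo1 and Akr1b8 of the jejunum did not differ by the test (95% intervals 0.09 to 0.42 and 0.16 to 1.01). NRF2 targets were higher in 14 of 21 in the kidney and 2 in the MLN, or 19 and 6 by list (FDR = 2.48e-08 and 0.00669). In the kidney ATF4 genes were higher in 6 of 12 (8, FDR = 7.96e-05) and zinc response genes in 2 of 4 (2 higher and 1 lower, 0.0137). Heat shock genes were called lower in the MLN (3 of 8, FDR = 5.63e-05), spleen (5, 0.000496), ILN (1, 0.0316), blood (1, 0.000835) and brain (0, 0.00252), with 3, 5, 3, 4 and 0 by list. Without dim genes the calls of the ILN (0.194) and brain (0.0803) ended. Hspa1b of the spleen was lower at -0.74 ± 0.18 and Aox1 higher at 0.57 ± 0.12, neither called without the 19 arrays (0.107 and 0.118). In the brain immediate early genes were lower in 2 of 11 (6 by list, 0.00909) and inflammatory NF-kB genes were called with 0 of 14 lower (1 by list, 0.0245). Called genes numbered 760 in the kidney (369 higher, 391 lower), 45 in the jejunum (12, 33), 295 in the MLN (78, 217). They numbered 13 in the ILN (1, 12), 174 in the spleen (126, 48), 14 in the brain (5, 9) and 1 in the blood (0, 1). In this order they were 1478, 144, 597, 66, 585, 72 and 1 with place and 480, 0, 153, 2, 187, 0 and 1 (limma, 1347 and 1119 unadjusted for 0) with the groups alone. Shared places gave 1245, 256, 487, 122, 364, 40 and 1. The spleen gave 1 without the 19 arrays and 76 without 12 h DMF+MEF replicate 33. Without 6 h DMF+MEF replicate 84 the jejunum gave 2.

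DMF+MEF and DMF alone at 179.2 mg/kg hold the same total mass. In the kidney Cbr3 was higher with DMF+MEF by 0.52 ± 0.10 and Nqo1 by 0.22 ± 0.06, the latter not called with place (0.057). There 9 of 21 NRF2 targets were higher, 12 by list (FDR = 0.0282, and 0.125 with place). Hmox1 of the kidney did not differ by the test (95% interval 0.06 to 0.69). In the jejunum NRF2 targets were lower with DMF+MEF in 3 of 21, 12 by list (0.00326), where Nqo1 and Akr1b8 did not pass alone (95% intervals -0.34 to -0.04 and -0.80 to -0.03). Nqo1 of the MLN was lower at -0.44 ± 0.11. Called genes numbered 1290 in the kidney (384 higher, 906 lower), 74 in the jejunum (23, 51), 2042 in the MLN (356, 1686), 141 in the spleen (75, 66) and 10 in the brain (2, 8). By limma they were 0 in the ILN and 0 in the blood (2195 and 1067 unadjusted). In the order kidney, jejunum, MLN, spleen, brain, ILN and blood they were 1579, 127, 1190, 934, 6, 0 and 0 with place and 602, 63, 2009, 4, 1, 1 and 0 (limma, 794 unadjusted for 0) with the groups alone. Shared places gave 873, 11, 419, 227, 58, 3 and 2. Without the 19 arrays the spleen gave 1. Without 6 h DMF+MEF replicate 85 it gave 56, and without 12 h DMF+MEF replicate 36 the kidney gave 826.

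Effects were compared between 12 and 6 h for the higher dose and MEF. In the kidney Hmox1 and Cbr3 changed less at 12 h, by -2.45 ± 0.28 and -1.30 ± 0.18 with DMF and by -3.23 ± 0.29 and -1.60 ± 0.18 with MEF, and Mt1 by -0.56 ± 0.09 with MEF. Nqo1 did not differ by the test (-0.27 to 0.18 and -0.33 to 0.13, 95% intervals). NRF2 targets were lower at 12 h in 10 of 21 with each (13 and 14 by list, FDR = 0.00346 and 0.000439). With MEF so were zinc response genes in 2 of 4 (2, 0.0165, and 0.055 after quantile normalization) and heat shock genes in 4 of 8 (6, 0.0348, and 0.0721 with place, 0.119 without dim genes and 0.0862 after quantile normalization). In the MLN Nqo1 changed less at 12 h with DMF, by -1.16 ± 0.22, as did 5 NRF2 targets (8 lower and 1 higher by list, 0.00301). There heat shock genes were lower in 1 of 8 (4, 0.0147, and 0.116 without dim genes). Nqo1 did not differ by the test in the jejunum (-0.55 to 0.00) or ILN (-1.08 to -0.12) with DMF, nor Akr1b8 in the jejunum (-1.14 to 0.29), nor Nqo1 in the MLN with MEF (-0.98 to -0.10). Interferon response genes of the blood were called with DMF (0 of 9 lower, 6 by list, 0.0441, and 0.633 with place, 0.121 without dim genes and 0.08 after quantile normalization). With the higher dose the effect differed for 1220 genes in the kidney (569 higher, 651 lower), 539 in the jejunum (198, 341), 446 in the MLN (290, 156). It differed for 655 in the ILN (425, 230), 1041 in the spleen (385, 656), 191 in the brain (46, 145) and 5 in the blood (3, 2). In this order these were 1369, 1109, 696, 975, 689, 521 and 3 with place and 145, 625, 16, 100, 1, 71 and 214 within shared places, and with the groups alone 1024, 473, 284, 883, 532, 85 and 2. Without the 4 arrays the jejunum gave 145, and without the 19 the spleen gave 479. The ILN gave 41 without vehicle replicate 1 of 12 h. With MEF they numbered 1262 in the kidney (488, 774), 3 in the jejunum (1, 2), 32 in the ILN (16, 16) and 2 in the brain (1, 1). By limma they were 0 in the MLN, spleen and blood (895, 898 and 906 unadjusted). In the order kidney, jejunum, ILN, brain, MLN, spleen and blood they were 1807, 4, 200, 8, 0, 1 and 0 with place and 1945, 0, 8, 0, 0, 0 and 0 (limma, 1202, 1006, 838, 1060 and 605 unadjusted for 0) with the groups alone. Shared places gave 1637, 2, 38, 13, 0, 0 and 4, and the ILN gave 4 without 12 h MEF replicate 32.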

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

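The named genes were chosen partly after the data had been seen. Genes that the higher dose affected differently at 12 and 6 h (limma's test) numbered 1220, 539, 446, 655, 1041, 191 and 5. The order is kidney, jejunum, MLN, ILN, spleen, brain and blood. For MEF the genes numbered 1262 in the kidney, 3 in the jejunum, 32 in the ILN and 2 in the brain.

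Single arrays stood apart from the rest of their group in 31 of 414 combinations of a named gene and a group, or 7.49 percent, where chance gives about 1 in 20. The value in parentheses is the gap to the nearest other array as a share of the range of the group, and levels are log2. In the kidney at 6 h higher-dose replicate 69 had S100a9 at 8.41 against 6.53 to 7.24 (0.623) and MEF replicate 78 had Slc6a15 at 8.84 against 7.26 to 7.79 (0.666). Vehicle replicate 55 had Gstm3 at 3.25 against 2.82 to 2.92 (0.781). In the kidney at 12 h lower-dose replicate 10 had Nqo1 at 9.26 against 9.75 to 9.92 (0.74), and higher-dose replicate 24 had Asns at 8.34 against 7.39 to 7.81 (0.566), Atf3 at 6.31 against 3.56 to 4.6 (0.623) and Trib3 at 5.4 against 3.53 to 4.26 (0.606). MEF replicate 31 had Cyp24a1 at 9.35 against 7.16 to 8.09 (0.575) and MEF replicate 28 had Hmox1 at 6.71 against 7.13 to 7.36 (0.634). MEF replicate 32 had Npas2 at 7.21 against 7.72 to 8.1 (0.577). In the jejunum at 6 h vehicle replicate 57 had Cbr3 at 4.89 against 3.87 to 4.13 (0.742) and vehicle replicate 51 had Hmox1 at 2.79 against 3.38 to 3.78 (0.594). In the jejunum at 12 h lower-dose replicate 14 had Akr1b8 at 9.39 against 6.82 to 7.71 (0.654) and Nqo1 at 9.7 against 8.73 to 9.08 (0.635). In the MLN at 12 h higher-dose replicate 24 had Fos at 7.32 against 6.51 to 6.8 (0.647) and vehicle replicate 8 had Zfp800 at 6.17 against 6.95 to 7.57 (0.555). In the ILN at 12 h higher-dose replicate 24 had Oas2 at 5.57 against 6.46 to 6.84 (0.7) and MEF replicate 32 had Nqo1 at 7.29 against 6.7 to 6.83 (0.782). Vehicle replicate 1 had Gbp2 at 10.38 against 8.79 to 8.91 (0.924). In the spleen at 6 h vehicle replicate 58 had Klf11 at 8.98 against 7.93 to 8.4 (0.551) and Rbm12b1 at 7.3 against 7.72 to 8.08 (0.546). In the spleen at 12 h higher-dose replicate 17 had Nqo1 at 8.22 against 6.79 to 7.28 (0.66). In the brain at 6 h vehicle replicate 53 had Ddx51 at 7.4 against 7.06 to 7.2 (0.603), and vehicle replicate 55 had Edil3 at 8.21 against 8.8 to 9.05 (0.702), Eif4a1 at 11.47 against 11.72 to 11.8 (0.76) and Fam81a at 8.34 against 8.98 to 9.16 (0.784). In the brain at 12 h DMF+MEF replicate 35 had Nqo1 at 8.82 against 7.47 to 8.03 (0.583) and vehicle replicate 7 had Lrrk2 at 5.63 against 6.14 to 6.41 (0.658). In the blood at 6 h higher-dose replicate 67 had Hmox1 at 6.11 against 7.08 to 7.51 (0.69). In the blood at 12 h higher-dose replicate 18 had Slfn8 at 7.99 against 8.51 to 8.73 (0.695) and vehicle replicate 5 had Dnajb1 at 9.54 against 9.84 to 10.07 (0.571). No explanation was tested for these arrays.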

How the results depend on the processing

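The choices were fixed before the data were examined, except the covariate for place in runs of 12, contrasts within shared places, and the leaving out of the jejunum and spleen arrays and of 1 kidney array, chosen after it. NRF2 targets kept their call in the kidney in all 8 comparisons with vehicle under dim genes left out, repeated quantile normalization, the preset correlation and place. Of 105 counts of called genes, limma with trend and robust variance moved 0 by over 1.5 times, repeated quantile normalization 14, leaving out dim genes 28, place as a covariate 57 and a fit of only the groups compared 74 (67 lower, 7 higher). With dim genes left out fewer genes are tested. For the other settings the cause was not tested. Where an alternative called 0 genes by limma, 341 to 2209 had an unadjusted p below 0.05. Counts that moved are given here, with lower and higher standing for the DMF doses, against naive for vehicle at 12 h, dosed groups set against each other over both times, and over time for the change of an effect from 6 to 12 h.

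Quantile normalization repeated gave these counts. MLN counts were at 12 h 7 (lower) and 39 (MEF), 144 (DMF+MEF against lower). ILN counts were at 6 h 2 (MEF) and 149 (DMF+MEF), 0 (lower against MEF), over time 19 (MEF). Spleen counts were at 12 h 5 (lower). Brain counts were at 12 h 35 (MEF), 10 (lower against MEF) and 12 (higher against lower). Blood counts were at 6 h 1 (lower), at 12 h 3 (MEF), 0 (DMF+MEF against lower). Dim genes left out gave others. Jejunum counts were 492 (lower against MEF) and 106 (DMF+MEF against lower). MLN counts were 222 (higher against lower). ILN counts were at 6 h 16 (higher), 0 (MEF) and 139 (DMF+MEF), 1 (higher against lower), over time 64 (MEF). Spleen counts were at 6 h 45 (lower), at 12 h 1 (lower) and 280 (MEF), 292 (DMF+MEF against lower), 217 (DMF+MEF against higher) and 380 (higher against lower). Brain counts were at 6 h 1 (lower) and 8 (MEF), and at 12 h 1 (lower), 136 (higher) and 7 (MEF). They were also 3 (lower against MEF), 22 (DMF+MEF against lower) and 2 (DMF+MEF against higher), and over time 0 (MEF). Blood counts were at 6 h 5 (DMF+MEF), at 12 h 3 (lower) and 0 (MEF), 2 (DMF+MEF against lower), over time 2 (higher).

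Place as a covariate gave these counts. Kidney counts were 878 (lower against MEF) and 1478 (DMF+MEF against lower). Jejunum counts were at 6 h 433 (DMF+MEF), and at 12 h 36 (lower) and 258 (MEF). They were also 36 (lower against MEF), 144 (DMF+MEF against lower) and 127 (DMF+MEF against higher), and over time 1109 (higher). MLN counts were at 6 h 17 (DMF+MEF), and at 12 h 56 (lower), 244 (MEF) and 1181 (DMF+MEF). They were also 76 (lower against MEF), 597 (DMF+MEF against lower), 1190 (DMF+MEF against higher) and 29 (higher against lower), and over time 696 (higher). ILN counts were at 6 h 3 (lower), 91 (higher), 6 (MEF) and 166 (DMF+MEF), and at 12 h 497 (lower), 1161 (higher), 624 (MEF) and 1205 (DMF+MEF). They were also 0 (lower against MEF), 66 (DMF+MEF against lower) and 1 (higher against lower), and over time 200 (MEF). Spleen counts were at 6 h 11 (lower), 2394 (higher), 1091 (MEF) and 266 (DMF+MEF), and at 12 h 1 (lower) and 466 (MEF). They were also 462 (lower against MEF), 585 (DMF+MEF against lower) and 934 (DMF+MEF against higher), and over time 689 (higher) and 1 (MEF). Brain counts were at 6 h 124 (higher) and 36 (MEF), and at 12 h 18 (lower), 119 (MEF), 552 (DMF+MEF) and 878 (against naive). They were also 0 (lower against MEF), 72 (DMF+MEF against lower), 6 (DMF+MEF against higher) and 5 (higher against lower), and over time 521 (higher) and 8 (MEF). Blood counts were at 6 h 11 (DMF+MEF), at 12 h 6 (higher) and 10 (against naive), over time 3 (higher).

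The groups alone gave these. Kidney counts were at 12 h 57 (lower), 742 (higher) and 966 (DMF+MEF), and 480 (DMF+MEF against lower), 602 (DMF+MEF against higher) and 584 (higher against lower). They were also over time 1945 (MEF). Jejunum counts were at 6 h 23 (lower), 944 (higher), 21 (MEF) and 273 (DMF+MEF), and at 12 h 15 (lower), 574 (higher), 1 (MEF), 98 (DMF+MEF) and 97 (against naive). They were also 146 (lower against MEF) and 0 (DMF+MEF against lower), and over time 0 (MEF). MLN counts were at 6 h 1 (lower), 0 (MEF) and 9 (DMF+MEF), and at 12 h 0 (lower), 916 (higher), 6 (MEF), 78 (DMF+MEF) and 2297 (against naive). They were also 153 (DMF+MEF against lower) and 31 (higher against lower), and over time 284 (higher). ILN counts were at 6 h 0 (lower) and 0 (MEF), and at 12 h 0 (lower), 157 (higher), 0 (MEF), 0 (DMF+MEF) and 303 (against naive). They were also 2 (lower against MEF), 2 (DMF+MEF against lower), 1 (DMF+MEF against higher) and 7 (higher against lower), and over time 8 (MEF). Spleen counts were at 6 h 0 (lower) and 98 (DMF+MEF), and at 12 h 0 (lower), 5 (higher), 52 (MEF), 188 (DMF+MEF) and 1079 (against naive). They were also 4 (DMF+MEF against higher) and 18 (higher against lower), and over time 532 (higher). Brain counts were at 6 h 1 (lower) and 0 (MEF), and at 12 h 0 (lower), 41 (higher), 3 (MEF) and 1 (DMF+MEF). They were also 8 (lower against MEF), 0 (DMF+MEF against lower), 1 (DMF+MEF against higher) and 141 (higher against lower), and over time 85 (higher) and 0 (MEF). Blood counts were at 6 h 1 (lower), 3 (higher) and 0 (DMF+MEF), and at 12 h 0 (lower), 0 (higher), 0 (MEF), 0 (DMF+MEF) and 1 (against naive). They were also 1 (lower against MEF), and over time 2 (higher).

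Jejunum counts that fell without the distal arrays were at 12 h 37 (lower), 270 (higher), 5 (MEF), 76 (DMF+MEF) and 27 (against naive). Over time they were 145 (higher) and 1 (MEF). Leaving out the 19 spleen arrays lowered most of these. Spleen counts were at 6 h 10 (lower), 2101 (higher), 4 (MEF) and 170 (DMF+MEF), and at 12 h 6 (lower), 50 (higher), 20 (MEF) and 115 (DMF+MEF). They were also 881 (lower against MEF), 1 (DMF+MEF against lower), 1 (DMF+MEF against higher) and 1 (higher against lower), and over time 479 (higher) and 1 (MEF).

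Leaving out 1 array of a group of up to 5, or in the kidney 12 h higher-dose replicate 24, gave these counts. Kidney ranges were 1237 to 1799 (DMF+MEF at 12 h), 617 to 942 (DMF+MEF against lower) and 826 to 1458 (DMF+MEF against higher). Others were 1495 (higher at 12 h), 1323 (higher against lower) and 1502 (higher over time). Jejunum ranges were 95 to 824 (lower at 6 h), 153 to 614 (lower against MEF), 2 to 139 (DMF+MEF against lower) and 94 to 151 (higher against lower). Further ones were 610 to 1670 (DMF+MEF at 6 h), 46 to 106 (DMF+MEF against higher), 23 to 430 (MEF at 6 h) and 2 to 4 (MEF over time). ILN ranges were 69 to 658 (MEF at 12 h), 0 to 14 (lower against MEF), 4 to 345 (MEF over time) and 44 to 734 (lower at 12 h). Further ones were 297 to 2677 (higher at 12 h), 170 to 982 (DMF+MEF at 12 h), 699 to 2907 (against naive at 12 h) and 41 to 1406 (higher over time). Spleen ranges were 396 to 721 (DMF+MEF at 6 h), 76 to 170 (DMF+MEF against lower) and 56 to 225 (DMF+MEF against higher). Others were 247 to 482 (DMF+MEF at 12 h) and 1356 to 3233 (against naive at 12 h). Blood ranges were 18 to 54 (against naive at 12 h).

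Gcnt1 of the jejunum turned to 0.049 with higher at 12 h without the distal arrays. Nqo1 turned in the spleen at 12 h to -0.025 with higher and place, and with DMF+MEF it ran from -0.047 to 0.017 without 1 array, the latter without DMF+MEF replicate 33. In the blood it turned to -0.026 for lower against MEF with place. None of these Nqo1 values was called. Calls of named genes ended in 98 with only the groups compared, 58 refits without 1 array, 29 with place, 23 without the spleen arrays, 20 with the mean of all probe sets, 12 without the jejunum arrays, 8 with quantile normalization and 1 with dim genes left out. Of the list results followed here, calls ended in 22 with dim genes left out, 14 with place, 7 without the spleen arrays, 5 with quantile normalization and 1 without the jejunum arrays. The preset correlation ended 0 and called 12 that were not called, place 2, dim genes left out 1 and quantile normalization 1.

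With the groups alone these named genes lost their call. Kidney genes were Slc6a15 (6 h MEF), Atf3 and Trib3 (12 h higher), Cyp24a1 (12 h MEF), Zbtb16 (12 h against naive), Nqo1 (DMF+MEF against higher). Jejunum genes were Akr1c19, Ccnjl, Ier5 and Myct1 (6 h MEF), Slc5a4b, Gcnt1 and Car12 (12 h higher), Dnase1, Ugt2a3, Gata4, Msmo1, Hoxb3, Slc30a1, Akr1b8 and Nqo1 (12 h MEF), Apoa4, Sqle and Akr1b8 (12 h against naive), Sh3d19 and Osbpl3 (lower against MEF), Cbr3 (DMF+MEF against lower). MLN genes were Ifi203 (6 h higher), Nqo1 (6 h MEF), Rbm12b1 and Fos (12 h higher), Abraxas1, Zxdc, Golph3l, Hspa1b, Tenm3 and Cebpd (12 h MEF), Nqo1 (12 h lower), Hspa1b (12 h DMF+MEF), Fos and Eda2r (12 h against naive), Nqo1 (DMF+MEF against lower). ILN genes were Zfp110 (6 h higher), Nqo1 (6 h lower), Cpa3, Cma1, Mcpt4, Oas3, Oasl1, Oas2 and Nqo1 (12 h higher), Cma1, Cpa3, Mcpt4, Xrn1, Gbp2 and Pfdn2 (12 h MEF), Hsp90aa1, Ccl3 and Cxcl10 (12 h against naive), Nqo1 (higher against lower), Nqo1 (12 h lower), Nqo1 (12 h DMF+MEF). Spleen genes were Nqo1 (6 h DMF+MEF), Aox1, Nab2 and Dnaja1 (12 h higher), Gstm1, Nol9, Mindy1, Cep55, Sec24a and Ell2 (12 h MEF), Hspa1b (12 h DMF+MEF), Hspa1b (DMF+MEF against lower). Brain genes were Fam81a, Edil3, Eif4a1, Egr2, Ddx51 and Wdr5 (6 h MEF), Per2 (12 h higher), Schip1, Nmnat2, Nr4a1 and Armh4 (12 h MEF), Nqo1 (12 h DMF+MEF). Blood genes were Mmp8, Slc40a1 and Piwil2 (6 h higher), Zkscan8, Adgrl1, Rnf103, Dnaja1, Slfn8, Eme2 and Dnajb1 (12 h higher), Dnajb1 (12 h against naive).

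No paired analysis was possible because groups compared within a tissue share no animal numbers. No other background correction was run, as probe-level files are not used. Changes from or to levels near the floor cannot be measured in full.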

Other observations

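Tests chosen after the result was seen were those of runs of 12, of a steady order and of treatment, those of acinar RNA by dose and of the spleen calls without arrays, and those of intestinal place and of the vehicle against naive calls. Beyond the lists of the report, 23 of 33 lists were called in 0 of 105 contrasts by camera with an estimated correlation. With the preset correlation 14 of these were called in at least 1 contrast, B cell markers, PPAR-alpha and fasting genes, T cell markers, cholesterol synthesis genes, circadian clock genes, distal nephron and medulla markers, enterocyte markers, macrophage and monocyte markers, neutrophil markers, pancreatic acinar markers, platelet markers, proliferation genes, skeletal muscle markers and smooth muscle markers. The remaining lists, AhR target genes, astrocyte markers, choroid plexus markers, erythroid markers, kidney injury genes, microglia markers, neuron markers, oligodendrocyte markers and proximal tubule markers, were called in 0 with either. All 90 calls with the estimated correlation held with the preset one, which gave 309.

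Tra2b and many other genes were related to place in runs of 12 animal numbers. Runs of 12 related to more genes than each of 13 other lengths in 7 of 7 organs. A score of place-related genes stepped over run ends by a median of 7.21 SD of other steps. Organs ran from 3.55 (blood) to 8.6 (brain), over 1 to 4 run ends each. Within groups at least 53.7 percent of score variance followed place. As these genes were chosen for place, neither decides against steady order or treatment. A lasting state of each animal cannot be told apart, as the score of an animal correlated between organs at a mean of 0.752 before and 0.111 after place was removed. Processing of arrays or RNA in runs of 12 may be the source, an open hypothesis, since the labels give no layout.

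Pancreas genes were high in 17 spleen arrays, all of which also had further pancreas genes over 2 log2 above the kept arrays, so pancreatic tissue in the sample is a candidate source. These were 2 of 15 arrays of the higher dose and 4 of 15 of vehicle (Fisher's exact p = 0.651, 2-sided). This pools 0 of 7 against 4 of 8 at 6 h with 2 of 8 against 0 of 7 at 12 h, which differ in direction, and leaves dosing open. Without the 19 arrays 51.9 percent of the genes called at 6 h with the higher dose were called again, against these arrays as their whole source. With MEF 0.5 percent were. There 4 calls remained and 5 of 69 other sets of 4 vehicle arrays gave as few (median 89, lowest 2), so fewer arrays and pancreas RNA cannot be told apart.

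Genes of the distal intestine were high in jejunum vehicle replicates 5, 6 and 7 at 12 h. All 3 lay below the other 5 in proximal and above them in ileal genes, so another intestinal place may have been sampled. Kept vehicle arrays also varied in ileal mean, from 4.71 to 11.79 at 6 h and 3.35 to 11.54 at 12 h. Without the 3 distal arrays and lower-dose replicate 15, 2.6 percent of the vehicle against naive calls recurred, with 27 in all. Of 55 other sets of 3 vehicle arrays, 0 gave as few (limma, lowest 28, median 609). Each kept a distal array, so array number alone stays open. Of 13 NRF2 targets called higher with the higher dose, 11 were called again, against these arrays as their source.

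Taken singly, chance can be excluded for 81 of 105 counts of called genes and not for 15, from 100 splits of the arrays of each contrast. The other 9 counts were 0 by limma, which every split reaches, so they cannot tell. The splits ignore place, so they leave a gradient of place open. In the brain at 6 h with the higher dose 1231 called genes came to 124 with place and 12 within shared places. The real count was above all others in 52. In the other 29 of the 81, 2, 3 or 4 splits gave as many, the real one included, and with 96 contrasts tested some of these can pass by chance. Splits reaching the real count are given for the 15, and are 100 for the 9. Pairs give the real and the highest other count, in the order lower, higher, MEF and DMF+MEF at 6 h, the same at 12 h, vehicle against naive, lower against MEF, DMF+MEF against lower, DMF+MEF against higher, higher against lower, and change with time of higher and of MEF. Kidney pairs were 695 and 109, 4267 and 2565, 1008 and 110, 2253 and 913, 236 and 278, 1240 and 731, 2991 and 1754, 1884 and 506. Then came 7871 and 5180, 2276 and 1, 760 and 131, 1290 and 128, 1016 and 197, 1220 and 776, 1262 and 451. Jejunum pairs were 447 and 409, 1473 and 539, 204 and 122, 1123 and 598, 108 and 227 (8 splits), 1266 and 772, 139 and 505 (5 splits), 590 and 982. Then came 930 and 886, 321 and 381, 45 and 59, 74 and 9, 84 and 54, 539 and 335, 3 and 1131. MLN pairs were 4 and 2, 67 and 12, 1 and 1, 31 and 6, 14 and 547, 2364 and 1061, 103 and 85, 725 and 307. Then came 4174 and 3837, 263 and 267, 295 and 46, 2042 and 396, 130 and 24, 446 and 684, 0 and 12. ILN pairs were 5 and 727 (6 splits), 40 and 19, 1 and 2 (13 splits), 74 and 5, 217 and 1207, 2110 and 706, 179 and 1282 (12 splits), 603 and 2698 (13 splits). Then came 2485 and 779, 4 and 8, 13 and 104, 0 and 5, 2 and 7, 655 and 95, 32 and 117. Spleen pairs were 25 and 2, 3927 and 1996, 598 and 12, 681 and 79, 3 and 370, 81 and 187, 158 and 145, 574 and 122. Then came 3130 and 1959, 1750 and 1, 174 and 920, 141 and 103, 220 and 578, 1041 and 346, 0 and 2. Brain pairs were 2 and 3 (7 splits), 1231 and 328, 21 and 32, 18 and 123, 4 and 1069 (18 splits), 224 and 14, 15 and 92 (7 splits), 248 and 1133. Then came 437 and 23, 1 and 53 (6 splits), 14 and 503, 10 and 313, 92 and 416, 191 and 2, 2 and 14. Blood pairs were 0 and 3, 12 and 55, 0 and 14, 1 and 73 (39 splits). Next came 6 and 107, 55 and 459 (5 splits), 1 and 9 (20 splits), 37 and 931 (9 splits). Then came 46 and 800 (6 splits), 0 and 0, 1 and 1, 0 and 1, 0 and 0, 5 and 1062, 0 and 1. In some contrasts another split called several times the real count, for a reason not tested.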
